A study of Oryza sativa with 4 samples.

How the data were processed

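RNA was taken from flag leaf blades at their widest part, from greenhouse plants of 2 genotypes, WT (TC65) and d1 (allele d1-1), with 2 libraries each, 4 in all. The labels give the plants' age both as 2 months and as 100 days of growth. Days had 16 h of light at about 500 μmol per square metre and second and averaged 30 °C, and nights were at 25 °C. Sequencing was on a HiSeq instrument. Per the labels, the libraries are biological replicates. Whether they came from separate plants, and whether equal replicate numbers mark a shared day, is not stated.

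Per the submitters' processing notes, the tools were FastQC, Trimmomatic, TopHat2, Cufflinks and Cuffdiff, with the rice build IRGSP-1.0; versions, order, parameters and annotation are not given in the sources used here. The only file is a gene table in the layout of Cuffdiff. Its FPKM columns, deposited by the authors, hold 1 value per genotype over its 2 libraries, with fragments divided by transcript length and by mapped fragments. The scaling between libraries is not given. The FPKM sums were 1144962 in WT and 1381426 in d1, a log2 ratio of 0.27, while the median log2 ratio of tested genes was -0.02, so sums and medians give different scales. The test statistic, a signed score, the p-value and the q-value per gene are those of the authors' deposited table. The smallest p-value in the authors' deposited table is p = 5e-05, shared by 1342 genes. The authors' significance mark equals a q-value under 0.05 in every row. Status was OK (tested) in 23672 rows, no test in 11994 rows and too much data in 1 row. A deposited log2 column holds no number in 1500 cells and was replaced by the log2 of the FPKM ratio, d1 over WT, with no pseudocount unless stated. The 61 identifiers found on more than 1 row (138 rows) were kept as separate rows.

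Since no value per library is given, no test across libraries could be run here, no interval for a fold change can be given and no share of counts has an interval. The labels state about 40000000 reads per library, but mapped reads and transcript lengths are not given in the sources used here, so the reads behind an FPKM value are known only roughly. A gene counted as changed if the authors' q-value was under 0.05. Cuffdiff's q-values in this table are smaller than, or equal to, a Benjamini-Hochberg adjustment of its p-values over the tested rows (0.000186 against 0.000882 at the smallest p in the authors' deposited table), and counts under both are given. "Called" always refers to the deposited q-values.

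The file uses locus identifiers of the rice annotation project without gene names, and matching to the reference table of gene symbols (assembly ASM3414082v1) ignoring case gave 1 match. Gene symbols are therefore not printed, and no coordinates are given. Among the genes chosen by size of change, only 2 that rose and 2 that fell are printed, by identifier. The intended rule, 12 genes each way with an informative description, could not be applied without descriptions. Before the data were examined, 33 gene lists had been fixed. Of these, 12 held locus identifiers (87 in all, every one found in the file), and the other 21 were defined by words of a description and could not be used. The identifiers on the lists, including that of RGA1, were entered from general knowledge and were not checked against an annotation. Classes within a list (such as cellulose synthase) follow the symbols entered with the list but were written down after the values had been seen. Markers of dividing cells, roots and reproductive organs were among the unusable lists, so other tissues in the samples were examined only through the secondary wall list. Chromosome and order were read from the identifiers, whose numbers run along each chromosome by convention.

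For each list of at least 5 tested loci, a two-sided Fisher's exact test compared the share of called loci, per direction, with all other tested genes, with Benjamini-Hochberg adjustment over 16 tests. Genes are not independent replicates, so these tests describe this table. The list's median log2 ratio was ranked among 10000 random lists drawn from the same of 20 bins of mean FPKM. Setting the FPKM sums equal shifts every log2 ratio alike, so it leaves these percentiles as they are. As an alternative, the number of called loci was set against 100000 random lists matched in the same way. Loci of smaller lists are given by value. Counts adjusted over the list alone use the deposited p-values of its tested loci. Positions were tested by 100000 random draws of tested loci. The calling step was tested on simulated FPKM pairs for the 23672 tested genes of d1 against WT, with 200 genes changed, in 40 simulations with an assumed spread. The simulated p-values came from that spread, the same for all genes, rather than from Cuffdiff. The rates below therefore check the calling step only and do not give the power of the deposited test. The calling step recovered 100% of genes changed by a log2 ratio of 2 or -2. At a log2 ratio of 1 it recovered 66.6% on average (52% to 82%), and at -1 it recovered 65.2% (52% to 80%). A planted list was found at percentile 100. Of 200 random lists in 1 simulation, 14 fell outside the central 95% of matched lists. Alternatives were a q of 0.01, a minimum of 2-fold, a minimum of 1 FPKM, the recomputed adjustment, centring on the median, 1 FPKM added to both groups, and, chosen after seeing the data, equal FPKM sums, leaving out repeated identifiers and, for the lists, the recomputed adjustment and the matched random lists. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.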

Results

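The transcriptome of rice flag leaf blades was compared between the wild type TC65 (WT) and the d1 mutant, with 2 biological replicates per genotype. TC65 is a japonica cultivar, and d1 is a dwarf mutant of RGA1, the gene for the alpha subunit of the rice heterotrimeric G protein. The comparison asks which leaf transcripts differ when RGA1 is mutated, and it is the only contrast in the design. The deposited table held 35667 rows of gene loci, with 1 FPKM value (fragments scaled by transcript length and by mapped fragments) per genotype and the authors' own test. The replicates had been combined before deposit, so neither a spread between libraries nor the depth of a library is known from the table, and no SD can be given. About 40000000 single-end reads of 150 bp per library are stated in the labels. Of the rows, 23672 had been tested, with a median of 7.80 FPKM in WT and 7.41 FPKM in d1.

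RGA1 itself was examined first. Its locus (OS05G0333200, chromosome 5 by its identifier) was read at 20.7 FPKM in WT and 17.3 FPKM in d1, a log2 ratio of -0.26 (-0.53 if both FPKM sums are set equal). The authors' deposited table gives p = 0.182 and q = 0.296 for this difference, so the difference did not pass the test. The value covers the whole locus and therefore does not show the lesion that the genotype label refers to. The gene groups below are lists of loci entered by identifier from general knowledge before the data were examined, and the pairing of locus and function was not checked against an annotation. Of the other 7 tested loci entered as G protein subunits or partners, 1 was called higher in d1, a signalling partner rather than a subunit, at 28.6 FPKM in WT and 41.4 FPKM in d1 (q = 0.0135 in the authors' deposited table). The remaining 6 did not pass. They included 3 loci of extra-large G proteins, related alpha-type proteins, at log2 ratios of -0.22, 0.07 and 0.24. The beta subunit locus was read at 16.3 FPKM in WT and 16.4 FPKM in d1. The 2 tested gamma subunit loci were read at 32.9 and 1.14 FPKM in WT and at 32.8 and 0.768 FPKM in d1. Adjusted over the list alone, the count of called loci was the same in this list and, unless stated, in those that follow. The list's median log2 ratio was 0.00 (-0.27 with equal FPKM sums) and its mean -0.02, with the median at percentile 47.5 of 10000 random lists matched on mean level.

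Across the leaf transcriptome, more genes were lower in d1 than higher. The q-values of the authors' deposited table called 4569 genes (19.3% of those tested), of which 2856 were lower in d1 and 1713 were higher. The lower genes had a median log2 ratio of -1.01 and the higher genes one of 0.81. A change of at least 2-fold was reached by 1486 of the lower and 639 of the higher genes, or by 2140 and 437 if both FPKM sums are set equal. When the adjustment was recomputed from the deposited p-values over the tested genes of this table, 3375 of the 4569 calls remained, 2170 lower and 1205 higher. The largest rises among called genes with at least 1 FPKM in both genotypes were at OS01G0850700, from 3.22 to 78.3 FPKM, and at OS03G0782200, from 27.9 to 637 FPKM. The largest falls were at OS11G0211800, from 145 to 1.34 FPKM, and at OS12G0247700, from 5915 to 97.2 FPKM. All 4 had the smallest p-value in the authors' deposited table, p = 5e-05, with q = 0.000186. The sources used here do not pair these 4 loci with gene names.

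**Figure D1:**
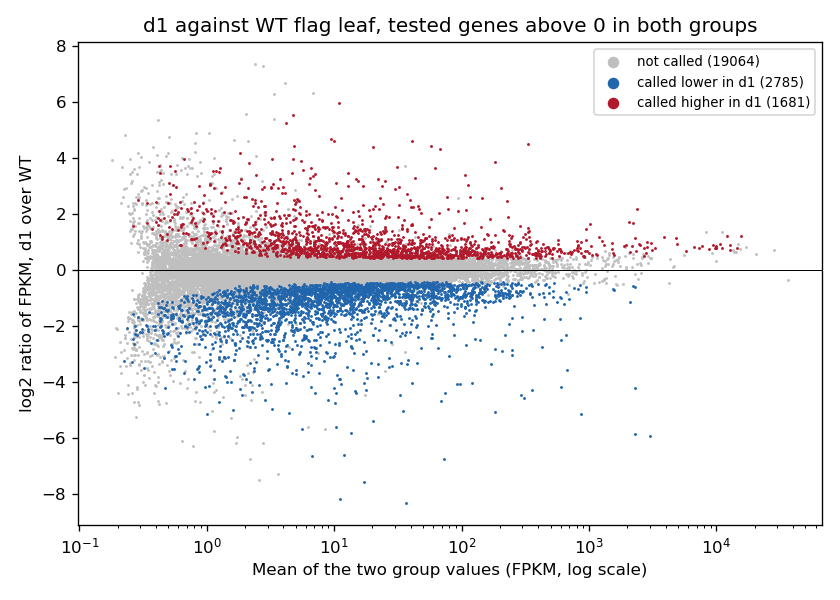
Log2 ratio of FPKM (d1 over WT) against the mean of the group values in FPKM on a log scale, for tested genes above 0 in both genotypes. Points are genes, coloured by the authors' call; the genes at the highest levels lie mostly above 0, while called genes over the rest of the range lie more often below it.

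The most abundant leaf transcripts went the other way from the bulk of the calls. Of the 100 genes with the highest mean level (1544 FPKM or more), 83 had a higher value in d1 (73 if both FPKM sums are set equal), with a median log2 ratio of 0.59 (0.32 with equal sums). Of these 100 genes, 40 were called higher, 8 were called lower and 52 were not called, by the q-values in the authors' deposited table. With the recomputed adjustment 25 were called higher and 7 lower. Together the 100 genes made up 39.8% of the FPKM sum in WT and 49.0% in d1. The 3 loci entered in advance as rubisco small subunits, the nuclear-encoded part of the carbon-fixing enzyme, belonged to this range. They were read at 21644, 6176 and 1757 FPKM in WT and at 35243, 15778 and 3301 FPKM in d1, with log2 ratios of 0.70, 1.35 and 0.91. The last was called in the authors' deposited table (q = 0.0161), and the other 2 did not pass. When the tested genes were divided into 10 equal groups by mean level, the share of calls that were higher in d1 was 30.8% in the bottom group, 22.4% in the group above it and 52.9% in the top group. In the top group these were 423 higher and 377 lower calls, and 312 and 324 with the recomputed adjustment.

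Several chlorophyll biosynthesis loci were called higher in d1. Of the 7 loci listed, all tested, 4 were called higher, none was called lower and 3 did not pass. Of the 2 loci of protochlorophyllide oxidoreductase, the enzyme of the light-dependent step, 1 rose 5.57-fold, from 69.6 to 388 FPKM, and the other was read at 320 and 435 FPKM without passing. Of the 3 loci for subunits of magnesium chelatase, which commits protoporphyrin to the chlorophyll branch, 2 rose, from 444 to 745 FPKM and from 433 to 723 FPKM, and the third was read at 121 and 137 FPKM without passing. Of 2 loci for later steps, 1 rose from 496 to 766 FPKM and the other was read at 72.3 and 60.2 FPKM without passing. Higher calls were more frequent in this list than among other tested genes, of which 7.22% were called higher (two-sided Fisher's exact test, p = 0.000801, adjusted p = 0.0128 over 16 tests on 8 lists). All 7 loci lay in the top group by mean level, where 17.9% of genes were called higher. Against random lists matched on mean level, the count of 4 had a one-sided permutation p of 0.0414, adjusted p = 0.435 over 16 tests, and so did not pass. The list's median log2 ratio of 0.63 (0.36 with equal FPKM sums) lay at percentile 98.9 of 10000 random lists matched on mean level. This percentile, like those of the other lists, was not adjusted over the 12 lists. With the recomputed adjustment, 2 of the 4 calls remained, and the Fisher's exact test did not pass either (adjusted p = 0.367).

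Loci of light protection and of chloroplast positioning were examined because both processes limit light damage in leaves. Of the 2 PsbS-type loci, whose protein triggers dissipation of excess light as heat, the abundant one was read at 2559 FPKM in WT and 3478 FPKM in d1 and did not pass, whereas the minor one fell 2.49-fold, from 73.6 to 29.6 FPKM (q = 0.000186 in the authors' deposited table). The 2 xanthophyll cycle loci had log2 ratios of 0.35 and 0.26 and did not pass. The median log2 ratio of these 4 loci was 0.30 (0.03 with equal FPKM sums) and their mean -0.07, with the median at percentile 82.5 of matched random lists. Of the 2 tested phototropin loci, blue-light receptors that steer chloroplast movement, 1 rose from 1.32 to 2.52 FPKM (q = 0.00190 in the authors' deposited table). The more abundant one was read at 183 and 247 FPKM and did not pass. A chloroplast positioning locus was read at 90.4 and 120 FPKM and did not pass either, and the median of these 3 loci lay at percentile 89.2. Of 7 carotenoid biosynthesis loci, 1 was called higher and 1 lower. The riser was 1 of 2 lycopene cyclase loci (128 to 195 FPKM) and the faller 1 of 3 phytoene synthase loci (30.2 to 18.8 FPKM). The list's median log2 ratio was -0.03 (-0.30 with equal FPKM sums), at percentile 26.6 of matched random lists, while its mean was 0.03, and neither direction passed Fisher's exact test (adjusted p = 0.884 for each).

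Loci of the secondary cell wall, which mark xylem and fibre cells of the leaf, included 3 that were called lower in d1 among 4 tested. The 3 cellulose synthase loci of the secondary wall were all called lower, from 8.47 to 1.93 FPKM, from 2.95 to 1.65 FPKM and from 1.54 to 0.599 FPKM. The remaining locus of the list was read at 1.82 and 0.855 FPKM and did not pass over all genes tested. Adjusted over the list alone, all 4 were lower. The list's median log2 ratio of -1.22 (-0.63 with 1 FPKM added to both groups) lay at percentile 1.21 of matched random lists. With 4 tested loci it was below the minimum of 5 set for a Fisher's exact test, and only 1 of the 3 calls remained with the recomputed adjustment. Of 6 loci of leaf senescence and chlorophyll breakdown, 2 were called lower, from 7.06 to 3.54 FPKM and from 5.41 to 2.32 FPKM, and both remained with the recomputed adjustment. The other 4, including both chlorophyll b reductase loci, did not pass. The adjusted p for lower calls in this list was 0.628 (Fisher's exact test).

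Among hormone loci, both listed gibberellin 20-oxidase loci, whose enzymes make the precursors of active gibberellin, rose, from 1.85 to 5.98 FPKM and from 11.2 to 19.2 FPKM. The other 5 tested gibberellin loci did not pass, among them the 3 receptor and signalling loci at log2 ratios of 0.31, 0.10 and 0.06. The tested gibberellin 2-oxidase locus, also among these 5, was read at 2.29 and 3.94 FPKM, a log2 ratio of 0.78. It narrowly missed the threshold (q = 0.0510 in the authors' deposited table). The log2 ratios of this list were above 0 at 7 of 7 loci, or at 4 of 7 if both FPKM sums are set equal, with a median of 0.31 (0.04 with equal sums) at percentile 95.8 of matched random lists. Of 7 tested brassinosteroid loci, 2 were called higher and 1 lower. Of the receptor and co-receptor loci, 1 rose from 4.59 to 9.55 FPKM and the other was read at 8.43 and 8.84 FPKM. A signalling locus rose from 0.420 to 1.48 FPKM. The faller was 1 of 3 tested synthesis enzymes, from 3.39 to 1.91 FPKM. With the recomputed adjustment, 1 of the 3 brassinosteroid calls remained. Of 6 tested loci of abscisic acid metabolism and drought response, 1 was called, an abscisic acid 8'-hydroxylase, which inactivates the hormone, from 0.190 to 2.36 FPKM. The other 2 hydroxylase loci had log2 ratios of 0.13 and 0.32 without passing. Higher calls were made at 2 of 7 gibberellin, 2 of 7 brassinosteroid and 1 of 6 abscisic acid loci, against 7.23% of other tested genes. On so few loci, this excess did not pass Fisher's exact test in the gibberellin list (adjusted p = 0.459), the brassinosteroid list (adjusted p = 0.459) or the abscisic acid list (adjusted p = 0.884). The medians of the brassinosteroid list (0.07) and of the abscisic acid list (0.05) lay at percentiles 69.1 and 63.8, and became -0.20 and -0.22 with equal FPKM sums.

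Clock and flowering loci were listed because many leaf transcripts swing over the day. Of 11 tested loci, 1 was called higher (39.5 to 56.4 FPKM), 1 of 5 pseudo-response regulators was called lower (10.6 to 5.94 FPKM), and 9 did not pass. The most abundant clock locus was read at 771 FPKM in WT and 905 FPKM in d1. The list's median log2 ratio was 0.19 (-0.09 with equal FPKM sums), at percentile 84.2 of matched random lists, and its mean was -0.01. Neither direction passed Fisher's exact test (adjusted p = 0.884 for higher and 1 for lower calls). Of 6 flowering-time loci, 2 were tested and neither passed. Over the 12 lists, 73 of 87 loci had been tested, of which 14 were called higher and 9 lower. With the recomputed adjustment these counts were 11 and 6.

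**Figure D2:**
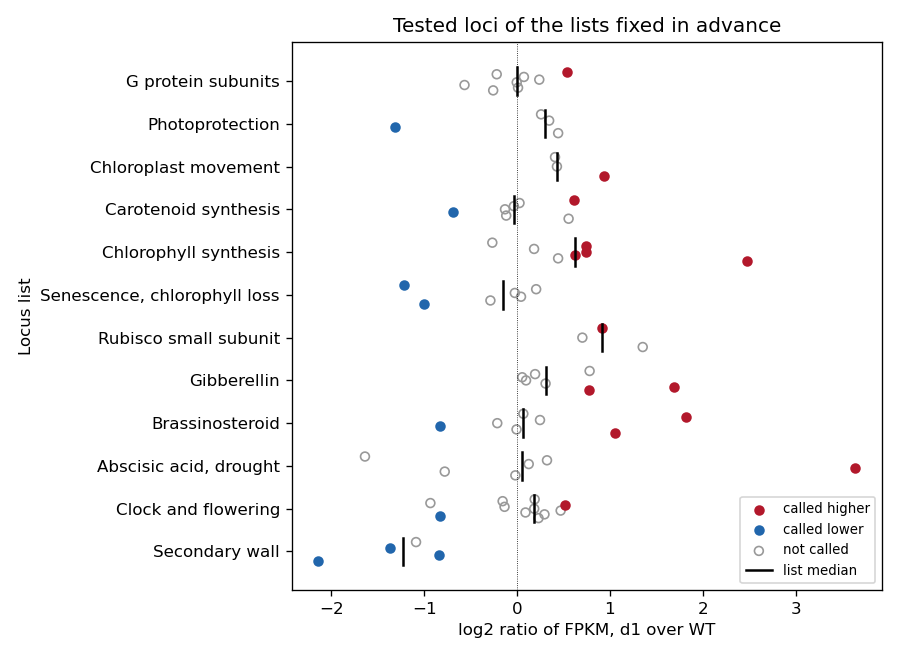
Log2 ratio of FPKM (d1 over WT) of each tested locus in the 12 lists fixed in advance. Filled points were called by the authors' q-values, open points were not, and the vertical bar is the list median; the chlorophyll synthesis loci lie mostly above 0 and the 4 secondary wall loci below it.

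Some genes were listed at 0 in 1 genotype only. Among called genes, 71 were listed at 0 in d1 and 32 at 0 in WT. Most were low in the other genotype, and 22 and 11 of them reached at least 1 FPKM there. The highest of the genes listed at 0 in d1 stood at 8.97 FPKM in WT. The 3 highest of the genes listed at 0 in WT stood at 13.3, 14.4 and 16.1 FPKM in d1. Their identifiers place all 3 on chromosome 5, at 110, 334 and 251 loci before RGA1. Another such gene, at 3.26 FPKM in d1, lay 351 loci before it. These genes and the window of 400 loci were chosen after the values were seen. So 4 of the 11 genes at 0 in WT and at least 1 FPKM in d1 lay within 400 loci of RGA1, where 0.234 would be met on average by random draws of tested loci. Of the 22 genes at 0 in d1 and at least 1 FPKM in WT, 1 lay in that window, 95 loci before RGA1. In the same window 101 of 504 tested loci were called, against 4468 of 23168 elsewhere.

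**Figure D3:**
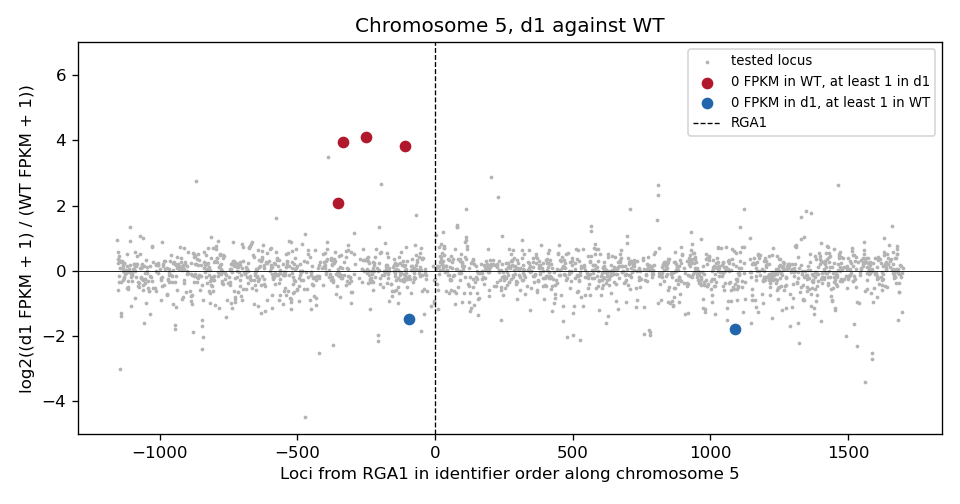
Log2 ratio of FPKM + 1 (d1 over WT) of tested loci along chromosome 5, in identifier order and counted in loci from RGA1 (dashed line). Red points are called genes at 0 FPKM in WT and at least 1 FPKM in d1, blue points the converse; the 4 red points lie between 351 and 110 loci before RGA1.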

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

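Among the 11994 rows without a test, which enter no comparison, 1 stood at 1 FPKM or more in d1 and above its WT value, at 1.45 FPKM against 1.08 FPKM. The rows without a test at 1 FPKM or more in WT and above d1 numbered 4.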

How the results depend on the processing

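Equal FPKM sums, leaving out repeated identifiers and, for the lists, the recomputed adjustment and random lists matched on mean level were chosen after seeing the data. No paired analysis was possible because the table holds 1 value per genotype, with no columns for the replicate numbers. For the same reason no library could be left out, no other split of the libraries could be formed, and the planned count tests, replicate block, per-library pseudocount, filter and scaling, and set tests across libraries were not run. A q under 0.01 called 2832 genes, 972 higher and 1860 lower, and 13 list loci in place of 23. It left 2 of the 4 called chlorophyll synthesis loci, and the list's adjusted Fisher's exact p became 0.493. Asking for at least 2-fold as well left 2125 genes, 639 higher and 1486 lower. The recomputed Benjamini-Hochberg adjustment left 3375 genes and 17 list loci, and the adjusted Fisher's exact p of the chlorophyll synthesis list became 0.367. Against random lists matched on mean level the adjusted permutation p of that list was 0.435, since its loci are abundant and abundant genes were more often called higher. Its adjusted p ranged from 0.0128 to 0.493 over the settings. With a minimum of 1 FPKM in 1 genotype or more, the calls numbered 4364 and the list's adjusted Fisher's exact p was 0.0172. Leaving out repeated identifiers gave 4546 calls. Lower calls outnumbered higher ones under all of these settings, with higher calls making up 30.1% to 37.8%. Centring on the median and equal FPKM sums cannot change the deposited calls, and changed the direction of none. Equal FPKM sums shift every log2 ratio down by 0.27, which takes the list medians of the G protein (-0.27), brassinosteroid (-0.20), abscisic acid (-0.22) and clock (-0.09) lists below 0 and RGA1 from -0.26 to -0.53, while the chlorophyll synthesis (0.36) and rubisco (0.64) medians stay above 0. Adding 1 FPKM to both groups took the secondary wall median from -1.22 to -0.63, since these loci are low. Mapped reads and transcript lengths are not given in the sources used here, so no counting error could be set beside low values.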

Other observations

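The patterns below were found in these data. The tests of shallow sampling, a chromosome segment, a scale offset, a few abundant genes, genotype, a constant rescaling of q and neighbouring loci were chosen after the result was seen, and that of chance placement before.

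Neighbouring loci changed together. Of 1117 adjacent pairs of tested loci in which both were called, 817 (73.1%) went the same way, against 53.0% of pairs in 1000 shuffles of the calls within chromosomes. The shuffles gave 883 called pairs on average, of which 468 went the same way, with at most 524 (permutation p = 0.001 for the number of pairs, the smallest these can give). The correlation of log2 ratios across pairs of loci, which are not independent replicates, was 0.185 for adjacent loci, 0.0594 at a distance of 2 loci, 0.0412 at 3 and 0.00638 at 50. Called genes made up between 17.1% (chromosome 2) and 21.1% (chromosome 5) of the tested loci of a chromosome.

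Of the 11 genes listed at 0 in WT and at 1 FPKM or more in d1, 4 lay within 400 loci of RGA1, among them the 3 highest, and 7 lay elsewhere. Zeros from shallow sampling of WT are argued against, since at the reads stated in the labels the d1 levels of these 4 genes equal at least 261 reads per kb over the 2 WT libraries if all reads map (26.1 if 10% map), and 3127 tested genes were read between 0 and 1 FPKM in WT. Chance placement along the genome stays open: of the 21 called genes at 0 in WT and under 1 FPKM in d1, which had no part in finding the pattern, 1 lay in the window against 0.447 expected (one-sided permutation p = 0.366), too few to decide. A candidate explanation is a chromosome segment of another parent carried with the d1 allele, which stays open as well: among the other 500 tested loci of the window, 5 were called with a change of 4-fold or more on the scale of FPKM + 1, against 232 of 23168 elsewhere (two-sided Fisher's exact p = 1), but parents may differ at few expressed genes. Failed estimates listed as 0 and an effect of RGA1 itself were not tested.

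More genes were lower than higher in d1, 2856 against 1713, with a median log2 ratio of -0.68 over the called genes. The median log2 ratio of all tested genes was -0.02, and a scale offset of that size is too small to be the whole cause. After centring on this median, 68.9% of the called genes at 2-fold or more were lower (1455 against 657). So small a shift could barely move these counts, so the centring by itself is no test of an offset. Whether a few abundant genes took reads from the rest is not decided by these values. On the deposited scale, the FPKM sum outside the 100 most abundant genes was not lower in d1, at 705123 against 689681 in WT. The 100 genes' share of the whole sum was 39.8% in WT and 49.0% in d1. With equal whole sums the rest would therefore be lower in d1. With the sums outside the 100 genes set equal, 71.7% of the called genes at 2-fold or more were lower (1553 against 614). That shift, 0.03 on the log2 scale, could only raise the share lower, so it cannot argue against this explanation. In both rescalings, which genes were called stays as deposited, and a change shared by most genes would not show in FPKM. The median log2 ratio of tested genes also rose with mean level, from -0.35 in the bottom of 10 groups to 0.08 in the top group. An offset that changes with level was not tested, and a constant shift does not address it. Genotype and any other difference between the 2 sets of plants cannot be told apart, because the design holds a single contrast and no value per library.

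The deposited q-values call 1194 genes that a Benjamini-Hochberg adjustment over this table does not. The ratio of deposited to recomputed q ran from 0.211 to 1, a 4.73-fold range, so q was not rescaled by a constant. Since both q-values meet at the largest p and were known to differ at the smallest, this outcome was fixed in advance. Read as a Benjamini-Hochberg adjustment, the deposited q at the smallest p would place 26.8% of all adjusted tests there. Of the genes tested here, 5.67% stood at that p, which argues against an adjustment over these genes alone. If a larger set of tests was adjusted together, the recomputed q-values are those of this comparison by itself, and the 1194 further calls would not pass in it. How the authors adjusted is not given in the sources used here, so whether such a set was used stays open. Under both, 3375 genes were called.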
